A study of Mus musculus with 3 samples.

How the data were processed

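Total RNA-seq libraries of the cytosolic fraction of mouse bone-marrow-derived macrophages were analysed from the tables the authors deposited, with no reads. Per the labels, 1 µg of RNA entered each library and 3 biological replicates form 1 group. The replicate numbers are those of the labels. All 3 carry the same donor entry, so p-values and SDs measure only the spread between these samples, which may be technical. Samples of other treatments, times or fractions were not used here, so no value is compared with a background and no change over time is stated.

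Per the file headers, the deposited gene and transcript tables hold an expected count per gene or transcript, a TPM value over all rows, and the posterior SD of the count. Their columns are laid out as those of RSEM, and they are called RSEM here for that layout. A second deposited transcript table per library holds an estimated count and TPM in the layout of kallisto, and is called so for the same reason. Per the text deposited with each library, the build was mm10 with the GENCODE M21 annotation, the first tables derive from alignments to the transcriptome and the second from the reads with an index. The aligner, quantifier and their versions are not given in the sources used here, nor is whether counting used strand, so values of overlapping antisense genes may share reads. All 55536 gene identifiers and 141862 transcript identifiers matched the annotation, and the second table held 141767 of the transcripts. Rows that name no annotated gene, 26248 with numeric identifiers, 96 spike-in controls and 1 for the phiX control genome, took 0.774%, 0.207% and 0.167% of expected counts in replicates 1, 2 and 3 and were left out of library sizes and tests. TPM divides by length, so short abundant RNAs take a large share and lower all others, and genes with near-identical copies divide their reads by model.

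Depth was 28759407, 54709008 and 49878183 expected counts in annotated genes. A count of 0 allows up to 3 counts, and limits from counts cover counting error only. Replicate 1, the shallowest, is the least precise for low genes.

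Gene lists, named genes, contrasts and tests were fixed before the data were examined. A gene counted as detected with at least 1 TPM in every library. For 9 contrasts the difference of the medians of log2(TPM + 1) of 2 lists was taken within each library, and its mean and SD over 3 libraries given. It was called when it had the same sign in all libraries and exceeded 3 SD, which held for 6. The two-sided exact sign-flip test cannot go below p = 0.25 with 3 libraries. As a description, each difference was set against 10000 random pairs of lists of the same sizes from detected genes, whereas the lists themselves keep undetected members. Differences on this scale understate those of low genes. Expected counts were rounded and scaled by TMM in edgeR 4.0.16 under R 4.3.3, and dispersions were estimated with an intercept alone after filterByExpr. Lists with at least 5 tested members were set against 10000 lists matched in 20 bins of mean expression. Counting noise was tested with a chi-square test of homogeneity on rounded counts given effective library sizes, for genes with a mean count of at least 10, with Benjamini-Hochberg adjustment. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Nuclear copies of mitochondrial genes were found with blastn 2.17.0 against the annotated transcripts, at an identity of at least 95% over at least 80% of the shorter sequence. GC content and length came from the most abundant transcript of each gene.

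Genes named are, per list, up to 4 detected members with the highest and 2 with the lowest mean TPM, 14 genes fixed in advance, the 10 highest nuclear protein-coding genes, the 10 with the highest dispersion over trend at a mean count of at least 100, and the 10 with the largest difference between quantifications at a mean of at least 10 TPM. Retnla, Arg1, Ly6g, Retnlg, mt-Co2, mt-Nd4l and the genes of the other observations were named after their values were seen, as were the 7SL genes. Not all genes that met these rules are reported here.

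The methods were tested on simulated data. With counting noise alone the chi-square test called 0.00754% of 13266 genes. Of genes changed in 1 library it called 64.0% at 1.2-fold, 98.0% at 1.5-fold and 100% at 2-fold, with 50 genes per fold. In that simulation of 200 changed genes it also called 0.804% of the unchanged genes. The changed genes had a mean count of at least 100, and library totals were used in place of TMM sizes. Power for lower genes was thus not measured. A simulated coefficient of variation of 0.16 was recovered as 0.160 over 13013 genes, and of 200 random lists 3% lay above the central 95% of matched lists. Alternatives were leaving out each replicate, pseudocount 0.1, detection at 0.1 or 5 TPM, detected members alone, list means, the kallisto table, TPM rescaled to nuclear protein-coding genes, DESeq2 1.42.0 size factors, no count filter and 10 expression bins. For TPM rescaled in this way, the nuclear protein-coding genes of a library sum to the same total. Chosen after seeing the data were the sum of mitochondrial genes with their nuclear copies, the rescaled ratio of the quantifications, and the alternatives for levels of named genes.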

Results

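The data comprised total RNA-seq, after depletion of ribosomal RNA, of the cytosolic fraction of mouse bone-marrow-derived macrophages. These are primary cells that are grown out of bone marrow precursors in culture, here of strain C57BL/6J. The cells had been exposed to 100 ng/ml Lipid A, the endotoxin part of lipopolysaccharide that activates Toll-like receptor 4 (TLR4), for 12 h. Lipid A was then washed out for 12 h, and a second exposure at the same 100 ng/ml lasted 30 min. The labels gave 1 group with 3 biological replicates, and the values describe which RNAs were abundant in the cytosol at this point and how far the replicates differed. Annotated genes received 28759407 expected counts in replicate 1, 54709008 in replicate 2 and 49878183 in replicate 3. Levels are given in TPM, the length-scaled share of transcripts in a library, as mean ± SD with n = 3 libraries unless stated, and positions refer to mm10. Without a second group, comparisons were made between gene lists within each library.

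The protein-coding genes of highest TPM were the ferritin chains Fth1 at 19397 ± 1275 TPM and Ftl1 at 8412 ± 1010.5 TPM, followed by the actin-sequestering thymosin Tmsb4x at 4827 ± 644 TPM, the chemokine Ccl5 at 4801 ± 98.1 TPM and the acute-phase gene Saa3 at 3937 ± 3395 TPM. The others of the 10 highest were Actb at 3703 ± 423 TPM, B2m at 3446 ± 450.4 TPM, Psap at 3411 ± 428 TPM, Lyz2 at 3194 ± 13.1 TPM and Ctsd at 2798 ± 236 TPM. Ccl5 and Lyz2 varied little between replicates, whereas Saa3 stood at 2622, 1396 and 7793 TPM in replicates 1, 2 and 3, and its mean without replicate 3 was 2009 TPM. At least 1 TPM in every library was reached by 9556 genes, 9080 of them protein-coding. The near-identical 7SL genes Rn7s1 and Rn7s2, the RNA of the signal recognition particle, were summed because reads cannot be assigned to either, and held 62.0% ± 3.56 of TPM but 9.46% ± 1.07 of expected counts (SD, n = 3). Nuclear protein-coding genes held 29.1% ± 1.07 of TPM and 87.6% ± 1.16 of expected counts.

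**Figure D1:**
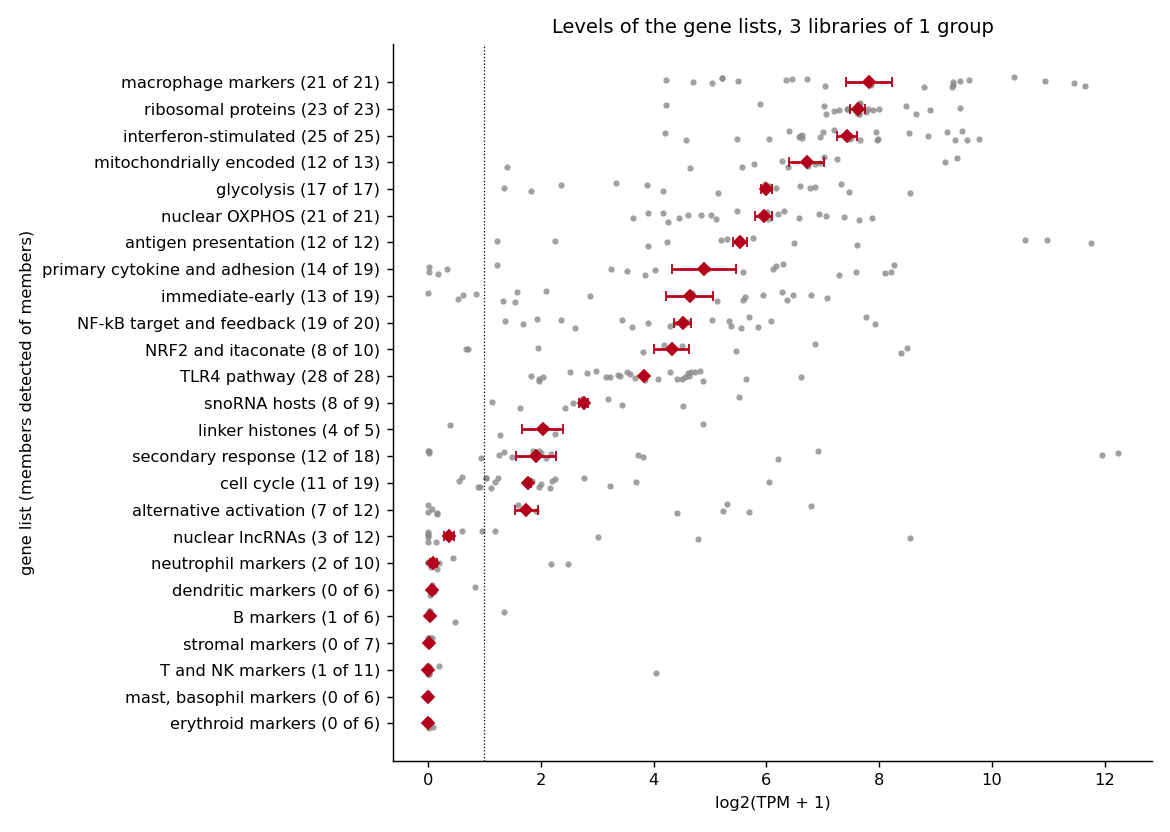
Levels of the gene lists fixed before the data were examined, on a log2(TPM + 1) axis: grey points are genes at their mean over 3 libraries, red diamonds with bars are the mean and SD over libraries of the list median, and the dotted line marks 1 TPM. Macrophage markers lie at 7.82 ± 0.41 and interferon-stimulated genes at 7.43 ± 0.18, above the secondary response list at 1.92 ± 0.35.

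Macrophage genes were abundant, and 48 of 52 markers of other cell types were not detected. All 21 macrophage markers were detected, from the lysozyme Lyz2 at 3194 ± 13.1 TPM and the cathepsins Ctsd at 2798 ± 236 TPM and Ctsb at 1963 ± 276 TPM and the Fc receptor gamma chain Fcer1g at 1345 ± 131 TPM down to the transcription factor Cebpa at 17.6 ± 5.72 TPM. The receptor for macrophage colony-stimulating factor, Csf1r (ENSMUSG00000024621.16, chromosome 18, 61100598 to 61132149), stood at 130.4 ± 27.2 TPM. Detected were 2 of 10 neutrophil markers, the calprotectin genes S100a9 at 4.61 ± 1.36 TPM and S100a8 at 3.53 ± 0.225 TPM, 1 of 11 T and NK cell markers, Cd4 at 15.5 ± 1.26 TPM, and 1 of 6 B cell markers, Cd79b at 1.53 ± 0.362 TPM. None of the 6 dendritic, 6 mast cell and basophil, 7 stromal and 6 erythroid markers was detected. A marker below this limit need not be absent. Of the 52 markers 9 had 0 counts in every library, and 4 of the 6 dendritic markers had a mean count of at least 10. The list medians differed by a log2 of 7.80 ± 0.40, a 222-fold difference on the scale of TPM + 1, with the macrophage list higher in 3 of 3 libraries (exact sign-flip p = 0.25, the smallest that 3 libraries allow). The size depends on the scale, with a log2 of 10.93 at pseudocount 0.1 and 5.50 among detected members alone. The difference of 7.80 lay above all 10000 random pairs of lists. Those pairs held detected genes alone, whereas 48 of the 52 markers were not detected, so nothing is read from this rank. Neutrophil genes Ly6g and Retnlg had 0 expected counts in every library, which allows up to 0.104, 0.0548 and 0.0601 CPM in replicates 1, 2 and 3, from counting error alone.

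The medians of the immediate-early and primary response genes lay above that of the secondary response genes 30 min into the second exposure. Of the immediate-early genes, which mostly encode transcription factors, 13 of 19 were detected, led by Junb at 133 ± 18.0 TPM, Klf6 at 109.9 ± 22.6 TPM, Atf3 at 88.1 ± 17.2 TPM and Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984) at 81.5 ± 24.3 TPM, with Egr2 at 3.26 ± 1.83 TPM and Myc at 2.00 ± 0.593 TPM the lowest of those detected. Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273) stood at 76.3 ± 39.7 TPM and ranged from 35.1 in replicate 1 to 114 in replicate 2. Of the primary cytokine and adhesion genes 14 of 19 were detected, led by Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) at 307 ± 139 TPM and the chemokines Ccl3 at 293 ± 102 TPM, Ccl4 at 273 ± 103 TPM and Ccl7 at 191 ± 63.3 TPM, with Cxcl1 at 10.6 ± 8.49 TPM and Ptgs2 at 8.43 ± 5.30 TPM the lowest detected. Il1b (ENSMUSG00000027398.13, chromosome 2, 129364570 to 129371139), which encodes a pro-inflammatory interleukin, stood at 47.1 ± 21.1 TPM, and Ifnb1 (ENSMUSG00000048806.4, chromosome 4, 88522025 to 88522774), the type I interferon gene induced by TLR4, at 1.32 ± 0.785 TPM.

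The secondary response list was split between a few very abundant members and many low ones. Ccl5, Saa3, the scavenger receptor Marco at 119.9 ± 52.1 TPM and the cytokine subunit Ebi3 at 73.2 ± 13.5 TPM led its 12 detected genes of 18, and Mmp13 at 2.65 ± 1.01 TPM and Ccl22 at 1.80 ± 0.543 TPM were the lowest detected. Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981) stood at 1.55 ± 1.02 TPM and was below 1 TPM in replicate 3, and Il10 (ENSMUSG00000016529.5, chromosome 1, 131019845 to 131024974), an anti-inflammatory cytokine, at 13.1 ± 3.72 TPM. Within libraries Tnf exceeded Il6 by a log2 of 7.88 ± 0.77 and Ccl5 exceeded Tnf by 4.09 ± 0.77, whereas Fos and Egr1 differed by -0.20 ± 1.04, less than their spread. The median of the immediate-early list exceeded that of the secondary list by a log2 of 2.72 ± 0.54 (6.61-fold on the TPM + 1 scale). That of the primary cytokine list did so by 2.97 ± 0.56 (7.86-fold). Each difference held in 3 of 3 libraries and exceeded 3 SD, with p = 0.25 in the two-sided exact sign-flip test. Both lay above all 10000 random pairs. Those pairs held detected genes alone, whereas 6 of the 18 secondary members were not detected, so nothing is read from these ranks. With the mean in place of the median, which gives Ccl5 and Saa3 their weight, both differences were within 3 SD, at 0.43 ± 0.38 and 1.10 ± 0.54.

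Genes that restrain the TLR4 and NF-kB response were detected beside the cytokines. Of the NF-kB target and feedback list 19 of 20 were detected, led by the mRNA-decay factor Zfp36 at 241 ± 53.8 TPM, the NF-kB inhibitor Nfkbia (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647) at 216 ± 73.7 TPM, the phosphatase Dusp1 at 66.5 ± 24.3 TPM and the cytokine-signalling suppressor Socs3 at 57.0 ± 19.4 TPM, with Socs1 at 2.82 ± 0.685 TPM and Dusp16 at 2.24 ± 0.570 TPM lowest. Tnfaip3 (ENSMUSG00000019850.11, chromosome 10, 19000910 to 19015657), which encodes the ubiquitin-editing enzyme A20, stood at 50.8 ± 14.9 TPM, and Nfkbia exceeded it by a log2 of 2.07 ± 0.21. The feedback minus the primary cytokine list gave -0.37 ± 0.47, with the sign shared by 2 of 3 libraries (exact sign-flip p = 0.50), so no difference was called. Among detected members alone the feedback list was lower by more than 3 SD, at -1.37 ± 0.33. All 28 TLR4 pathway genes were detected, from the co-receptor Cd14 at 97.0 ± 31.1 TPM, the adaptor Myd88 at 49.1 ± 4.89 TPM and the kinase Mapk14 at 28.5 ± 1.43 TPM to Tirap at 2.93 ± 0.30 TPM and Mapk8 at 2.53 ± 0.198 TPM. Tlr4 (ENSMUSG00000039005.13, chromosome 4, 66827584 to 66930284) itself stood at 23.3 ± 4.25 TPM, and the list median was 3.83 ± 0.02 on the log2 scale.

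**Figure D2:**
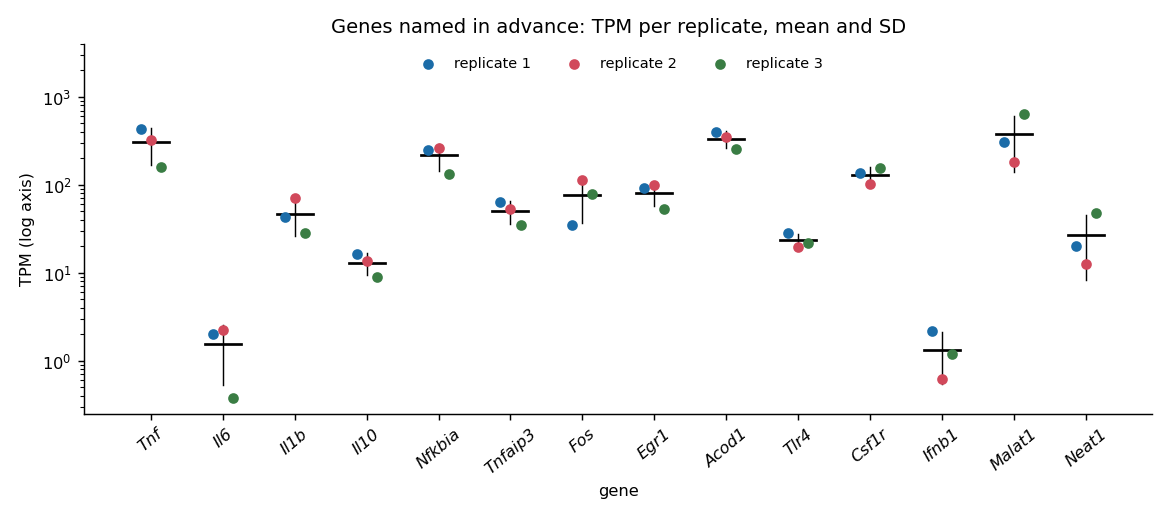
TPM on a log axis of the 14 genes named in advance, per replicate (coloured points), with the mean (horizontal line) and SD (vertical line) over 3 libraries. Tnf, Nfkbia and Egr1 lie lowest in replicate 3, at 159, 131 and 53.6 TPM, and Malat1 lies highest there, at 638 TPM.

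Interferon-stimulated genes were abundant as a group. All 25 were detected, 15 of them above 100 TPM in every library, led by the antiviral Ifit2 at 875 ± 215 TPM and Rsad2 at 747 ± 225 TPM, the transcription factor Irf7 at 708 ± 97.1 TPM and the ubiquitin-like Isg15 at 648 ± 131 TPM. The lowest were Mx2 at 22.9 ± 3.66 TPM and Oas2 at 17.3 ± 4.02 TPM. Their median exceeded that of the secondary response list by a log2 of 5.52 ± 0.23 (45.7-fold on the TPM + 1 scale) in 3 of 3 libraries (exact sign-flip p = 0.25). This lay above all 10000 random pairs, but those held detected genes alone and the secondary list did not, so nothing is read from the rank. The difference exceeded 3 SD under all 8 alternatives tried, from 4.12 with list means to 5.91 with pseudocount 0.1. Ifnb1 itself stood at 2.17, 0.620 and 1.18 TPM in replicates 1, 2 and 3.

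Of the genes of alternative activation, the state macrophages enter with interleukin 4, some were detected and others were near 0. Of 12 members 7 were detected, led by Tgfb1 at 109.7 ± 8.51 TPM, Stab1 at 50.7 ± 16.6 TPM, the interleukin 4 receptor Il4ra at 38.4 ± 12.8 TPM and the interleukin 1 antagonist Il1rn at 36.6 ± 12.0 TPM, with Clec10a at 2.78 ± 0.372 TPM and Chil3 at 2.04 ± 0.643 TPM lowest. Retnla, a classic marker of this state, had 0 expected counts in every library, and Arg1, another, had 2 expected counts in replicate 3 and 0 in the others. The list median minus that of the primary cytokines was -3.14 ± 0.55, negative in 3 of 3 libraries (exact sign-flip p = 0.25), but among detected members the difference, -0.79 ± 0.93, was within its spread. All 12 antigen-presentation genes were detected, led by B2m, with 2004 ± 274 TPM for the class I gene H2-K1 and 1526 ± 206 for H2-D1 against 195 ± 12.9 for Cd74, the invariant chain of class II. The costimulatory gene Cd80 at 3.77 ± 0.575 TPM and the class II regulator Ciita at 1.34 ± 0.116 TPM were lowest. Of the NRF2 and itaconate list 8 of 10 were detected, led by the peroxiredoxin Prdx1 at 359 ± 85.6 TPM, Acod1 (ENSMUSG00000022126.6, chromosome 14, 103046977 to 103056573), which encodes the enzyme that makes itaconate, at 335 ± 74.6 TPM, Hmox1 at 115 ± 22.8 TPM and G6pdx at 42.8 ± 6.06 TPM, with Gclm at 13.0 ± 3.74 TPM and Gclc at 2.87 ± 0.644 TPM lowest.

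Glycolytic and nuclear-encoded respiratory genes were all detected. The 17 glycolytic genes were led by Gapdh at 373 ± 55.0 TPM, Aldoa at 175 ± 16.5 TPM, Pkm at 159 ± 3.01 TPM and Ldha at 115 ± 5.44 TPM, with the glucose transporter Slc2a1 at 2.55 ± 0.413 TPM and Pfkm at 1.54 ± 0.0709 TPM lowest. The 21 nuclear-encoded respiratory genes ran from Atp5b at 232 ± 7.81 TPM, Cox4i1 at 199 ± 11.8 TPM, Cox5a at 166 ± 1.93 TPM and Cox6c at 132 ± 6.91 TPM to Ndufs1 at 14.0 ± 0.304 TPM and Ndufv1 at 11.4 ± 0.201 TPM. The list medians differed by 0.05 ± 0.09, less than the spread (exact sign-flip p = 0.75), whereas the list means put glycolysis lower by more than 3 SD, at -0.41 ± 0.04. Ribosomal protein genes were all detected, 21 of 23 above 100 TPM in every library, led by Rps24 at 692 ± 97.7 TPM, Rplp1 at 477 ± 57.4 TPM, Rpl19 at 402 ± 32.2 TPM and Rpl10 at 356 ± 61.9 TPM, with Rps3 at 57.9 ± 3.43 TPM and Rpl5 at 17.7 ± 0.329 TPM lowest. The levels of Rpl10 and Rpl5 rest on 1 quantification, since the second gave 30.1 ± 8.76 and 2.37 ± 0.560 TPM, lower by more than its general difference in scale.

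Mitochondrially encoded transcripts were detected for 12 of 13 protein genes. The highest were mt-Atp8 at 662 ± 142 TPM, mt-Co1 at 570.3 ± 168 TPM, mt-Nd6 at 151 ± 63.8 TPM and mt-Nd1 at 128 ± 38.2 TPM, and the lowest detected were mt-Nd3 at 46.3 ± 6.99 TPM and mt-Atp6 at 24.1 ± 14.5 TPM. The second quantification put mt-Atp8 at 131 ± 16.9 and mt-Atp6 at 104 ± 11.5 TPM. The median of the mitochondrially encoded list exceeded that of the nuclear-encoded respiratory list by 0.77 ± 0.44 in 3 of 3 libraries (exact sign-flip p = 0.25), which was within 3 SD and not called. Without replicate 3 the difference was 0.51 ± 0.04 over 2 libraries, more than 3 SD. The values of mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l are uncertain, because nuclear copies annotated as pseudogenes, of at least 95% identity, held from 50.8% (mt-Nd3) to 99.6% (mt-Co2) of the expected counts of gene and copies together. The order of levels given above depends on this assignment. The copies Gm28661 of mt-Co2, Gm10925 of mt-Atp6 and Gm28437 of mt-Co3 stood at 437, 251 and 249 TPM, each above mt-Nd6. With the copies added, the difference from the nuclear-encoded list was 1.22 ± 0.69, still within 3 SD.

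Of the list of nuclear long noncoding RNAs 9 of 12 members were not detected, and the median was 0.31 TPM. No other fraction was used here, so whether fractionation lowered these RNAs or the cells express little of them cannot be told. The 3 detected were Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) at 375 ± 236 TPM, Neat1 (ENSMUSG00000092274.3, chromosome 19, 5824708 to 5845478) at 26.8 ± 18.5 TPM and Xist at 7.07 ± 4.39 TPM. Malat1 exceeded Neat1 by a log2 of 3.84 ± 0.09 in 3 of 3 libraries. Without replicate 3 their means were 243 and 16.3 TPM. Of the hosts of small nucleolar RNAs 8 of 9 were detected, led by Gas5 at 44.7 ± 4.27 TPM, Snhg6 at 21.9 ± 4.09 TPM, Snhg8 at 9.84 ± 0.919 TPM and Snhg12 at 8.14 ± 0.458 TPM, with Snhg3 at 4.37 ± 1.27 TPM and Snhg5 at 2.12 ± 0.0551 TPM lowest. The nuclear minus the host list gave -2.39 ± 0.12, negative in 3 of 3 libraries (exact sign-flip p = 0.25), but with detected members alone the sign turned, at 1.61 ± 1.00. Cell-cycle genes were low, with 11 of 19 detected, led by Pcna at 64.7 ± 4.89 TPM, Mcm6 at 11.9 ± 1.46 TPM, Mcm3 at 8.38 ± 0.670 TPM and Cdk1 at 5.80 ± 0.571 TPM, and with Mcm7 at 2.59 ± 0.352 TPM and Tyms at 1.37 ± 0.0608 TPM lowest. Linker histone genes, whose mRNAs mostly lack poly(A) tails, were detected for 4 of 5 members, with Hist1h1c at 28.4 ± 3.86 TPM above Hist1h1a at 3.75 ± 1.30 TPM, Hist1h1e at 3.28 ± 1.01 TPM and Hist1h1b at 1.42 ± 0.225 TPM.

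Some of the gene lists shifted together in 1 replicate against the mean of the others, a comparison of single libraries that allows no test. For each gene the log2 ratios of the replicates cancel out, so shifts of a list in different replicates are not independent. In the immediate-early, feedback and primary cytokine lists, pooled after their values were seen, 49 of 54 genes with a mean count of at least 10 were lower in replicate 3, with a median log2 ratio of -0.74 after TMM scaling. Among them were the neutrophil-attracting chemokines Cxcl1 (-3.04) and Cxcl2 (-2.43), Tnfsf9 (-2.77) and Tnf (-1.27), whereas Fos had a ratio of 0.02. Of the secondary response list 8 of 15 members were lower, at a median of -0.11, with Saa3 at 2.03 and Marco at 0.96. Interferon-stimulated genes had a median of -0.01 in this library. Also in replicate 3, 9 of 10 NRF2 and itaconate genes (-0.47) and 22 of 23 ribosomal protein genes (-0.19) were lower and 12 of 13 mitochondrially encoded genes higher (0.66). All 7 nuclear long noncoding RNAs with enough counts were higher in replicate 3, at a median of 1.06, and lower in replicate 2, at -1.25, the largest shift of any list. In replicate 2 all 25 interferon-stimulated genes were lower (-0.35), all 10 NRF2 and itaconate genes higher (0.60) and all 23 ribosomal protein genes higher (0.24). In replicate 1 all 25 interferon-stimulated genes (0.34) and 15 of 16 primary cytokine genes (0.74) were higher and 12 of 13 mitochondrially encoded genes lower (-0.54). With DESeq2 size factors and with TPM rescaled to nuclear protein-coding genes, these medians kept their signs, except that of interferon-stimulated genes in replicate 3.

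**Figure D3:**
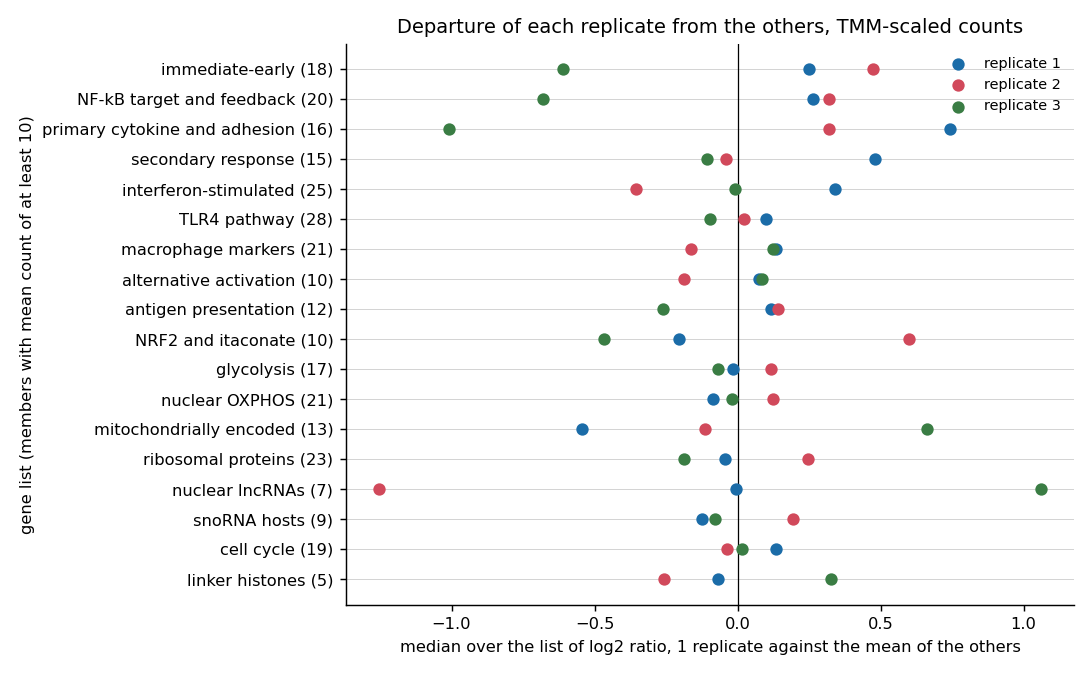
Median over each list of the log2 ratio of 1 replicate to the mean of the others, from TMM-scaled counts, for lists with at least 5 members with a mean count of at least 10 (number in brackets). Replicate 3 lies lowest for the primary cytokine list, at -1.01, and highest for nuclear lncRNAs, at 1.06.

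The common biological coefficient of variation was 0.157 over 12738 genes. The dispersion of the primary cytokine, secondary response, NRF2 and itaconate, mitochondrially encoded and nuclear long noncoding lists exceeded that of all 10000 random lists matched on mean expression, with median log2 dispersion over trend of 1.98, 1.39, 0.86, 0.95 and 2.10. The immediate-early (0.87) and feedback (0.81) lists did too, but without replicate 3 they were at percentiles 66.2 and 64.2. Interferon-stimulated genes lay at percentile 99.9, and at 87.3 without replicate 1 and 80.7 without replicate 2. Alternative-activation genes lay at 99.98, at 48.3 without replicate 1 and 93.6 without replicate 3. The TLR4 pathway (33.98), macrophage (41.3), nuclear-encoded respiratory (23.5) and small nucleolar RNA host (20.1) lists lay within the central 95% of matched lists, as did antigen presentation (88.8), glycolysis (93.8), ribosomal protein (91.0), cell cycle (94.0), linker histone (96.6) and other cell type (71.4) lists. Without replicate 1 antigen presentation, glycolysis and ribosomal protein genes lay above the central 95%, at 99.2, 99.4 and 98.4. The matched lists were drawn gene by gene, whereas members of a list can move together, so these percentiles are a description and no test. Part of the spread of the mitochondrially encoded list is open to how reads were divided with nuclear copies.

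The 10 genes most variable for their abundance were Gm20721, Lrrc14b, CT010467.1, Tnfsf9, mt-Co3, Cxcl1, the cell-cycle inhibitor Cdkn1c, Cxcl2, the nuclear receptor Nr4a1 and the prostaglandin synthase Ptgs2. Gm20721 stood at 1.24 TPM in replicate 1 against 14.1 and 16.5 in the others. The second quantification gave it 0.252 ± 0.0678 TPM and the posterior SD of its count was 31.9% of the count. For mt-Co3 the posterior SD was 94.5%, and its nuclear copy held 69.3%, 93.5% and 69.1% of the expected counts of both in replicates 1, 2 and 3. The spread of these genes is thus open to how reads were assigned. Lrrc14b stood at 5.67 against 1.10 and 0.420 TPM. Without replicate 1 the mean of CT010467.1 went from 132 to 85.1 TPM, and without replicate 3 that of mt-Co3 from 76.8 to 48.4 TPM. Cdkn1c and Nr4a1 were highest in replicate 2, at 9.81 and 4.34 TPM against means of 1.71 and 0.705 in the others. Cxcl1 stood at 11.3, 18.6 and 1.70 TPM, and Ptgs2 at 7.91, 14.0 and 3.41, in replicates 1, 2 and 3. Without replicate 2 the mean of Cxcl1 was 6.51 TPM, and without replicate 1 that of Lrrc14b was 0.760 TPM. By a chi-square test of counts with Benjamini-Hochberg adjustment at 0.05, 8691 of 13410 genes differed between the 3 libraries beyond counting noise, and 5547 did without replicate 3. Between 5547 and 7132 genes differed in each pair of libraries, so none was a second deposit of another.

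Each library was quantified in 2 ways, from alignments to the transcriptome and from the reads with an index. Across genes, which are not independent replicates, the Spearman rank correlation between the gene TPM of the first and the second was 0.838 ± 0.0118 (SD, n = 3). For detected protein-coding genes the median log2 ratio of the second to the first was -0.95 ± 0.25, and after rescaling both to nuclear protein-coding genes 0.609% ± 0.0509 of them differed by more than 2-fold. Of the 10 largest differences, Gm12896 and Gm12895 were at 0 in the first table and at 166401 ± 54186 and 166360.0 ± 54208 TPM in the second, and the genes annotated as microRNAs Gm24245, Gm24270 and Gm23935 at 0 and at 93846 ± 16967 each. These 5 entries took 53.9% to 71.6% of the TPM of the second table. Mir6236 and Gm17374 were likewise higher in the second table, at 617 ± 410.0 and 98.9 ± 80.4 TPM against 0. Gm10076, Gm26716 and Gm10222 were higher in the first, at 341 ± 35.8, 131 ± 18.5 and 115 ± 30.8 TPM against less than 1.

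Of the 17 genes examined for isoforms, 5 had a transcript with over 90% of the gene's TPM and 7 had none above 60%. Of the TPM of its gene, Tnf-201 100.0% ± 0.00705, Myd88-201 99.3% ± 0.432, Tlr4-201 98.0% ± 0.398, Ly96-201 97.8% ± 0.429 and Nfkbiz-204 96.1% ± 0.396 held nearly everything, followed by Pkm-201 84.4% ± 0.416, Fos-201 81.4% ± 12.3, Irak2-201 77.3% ± 3.75, Il1rn-201 74.9% ± 2.17 and Tnfaip3-201 66.0% ± 5.14 (SD, n = 3). Pkm-202 held a further 14.5% ± 0.715. A second Fos transcript without a coding sequence in the annotation, Fos-202, held 18.3% ± 12.4, and the share of Fos-201 was 67.6% in replicate 3. Cd44 was divided between Cd44-203 at 50.9% ± 1.99 and another coding transcript at 47.1% ± 2.36, and the leukocyte phosphatase Ptprc between Ptprc-203 at 45.3% ± 5.21 and Ptprc-204 at 45.1% ± 3.49, with overlapping SDs. Zfp36-201 58.9% ± 3.66, Irak1-206 47.9% ± 4.92, Nfkb1-206 46.5% ± 2.74 and Il15-202 40.8% ± 1.40 were the main transcripts of the remaining genes. For Nfkb2 the first quantification put Nfkb2-201 first, at 52.2% ± 2.79, and the second put Nfkb2-202 first, so its main isoform is not settled.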

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

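Reads of the phiX genome, a control added to sequencing runs, appeared in the deposited gene tables outside the measured genes, above the limit of 3 counts that a count of 0 allows. They took 0.774% of expected counts in replicate 1 (exact Clopper-Pearson 95% interval 0.770% to 0.777%), 0.207% in replicate 2 (0.206% to 0.208%) and 0.167% in replicate 3 (0.166% to 0.168%). The 96 spike-in rows held 0 counts in every library.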

How the results depend on the processing

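The summing of nuclear copies and the rescaled quantifier ratio were chosen after seeing the data. All 9 list contrasts kept their sign without any single replicate except glycolysis against nuclear-encoded respiratory genes (-0.01 to 0.08). A contrast with 1 sign in all 3 libraries must keep it. All moved by less than 1 SD, which is bound to hold for a mean of 3 libraries when 1 is left out. The mitochondrially encoded contrast exceeded 3 SD without replicate 3. The interferon-stimulated minus secondary contrast was 5.91 with pseudocount 0.1, 4.60 with detected members alone, 5.03 with kallisto, 5.82 with rescaled TPM and 4.12 with list means. The macrophage minus other cell types contrast was 10.93, 5.50, 6.88 and 9.52 under the first 4 of these. Nuclear long noncoding RNAs minus hosts of small nucleolar RNAs gave -4.09 with pseudocount 0.1, -1.60 with kallisto, -3.44 rescaled and -1.45 with list means, and reversed to 1.61 with detected members alone, where 3 of 12 nuclear members remain. Detected members alone also gave -1.37 for feedback minus primary cytokine genes and -0.79 for alternative activation minus primary cytokine genes. List means gave 0.43 for immediate-early and 1.10 for primary cytokine minus secondary genes, -1.77 for alternative activation and -0.41 for glycolysis. Adding the nuclear copies moved the mitochondrially encoded contrast to 1.22. Apart from member selection, list means and added copies, which act by construction, the cause was not tested.

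At 5 TPM 5890 genes were detected, at 0.1 TPM 12519, and with 1 replicate left out 9648 to 9691. The kallisto table gave 7997 and rescaled TPM 11158, so the number detected depends on the scale of TPM. The common coefficient of variation ranged from 0.138 to 0.177 with 1 replicate left out, and was 0.157 with DESeq2 size factors. Genes varying beyond counting noise ranged from 5547 to 7087 with 1 replicate left out, where fewer libraries are compared, and the kallisto counts gave 11421. With 1 replicate left out, the percentile of the spread ranged from 48.3 to 99.99 for alternative activation, 66.2 to 100 for immediate-early, 64.2 to 100 for feedback, 80.7 to 100 for interferon-stimulated, 16.9 to 99.2 for antigen-presentation, 13.0 to 99.4 for glycolysis and 3.92 to 98.4 for ribosomal protein genes. The Spearman rank correlation between quantifications was 0.931 over genes with at least 1 TPM by either, and the median log2 ratio went to -0.00240 after rescaling. Leaving out 1 of 3 libraries cannot move a mean by 1 SD, so it was no check of the 17 main isoform shares by that measure. With kallisto 13 of them moved by more than 1 SD, to 36.9% for Irak1, 67.5% for Irak2, 89.5% for Tlr4, 96.0% for Ly96, 40.1% for Nfkb2, 93.9% for Nfkbiz, 58.4% for Tnfaip3, 83.3% for Pkm, 72.2% for Zfp36, 52.9% for Cd44, 62.1% for Fos, 31.9% for Il15 and 99.9% for Tnf. Of 138 named genes, 124 moved by more than 1 SD with kallisto. With rescaled TPM all did except those at 0 TPM in every library, which stayed at 0. Both alternatives change the scale. By this measure leaving out 1 replicate could move none of them. Depth limits low genes most in replicate 1.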

Other observations

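The pooling of 3 response lists and the test of scaling and dilution were chosen only after the result was seen. Some further genes were picked by hand after their values were seen and stand for no class. Among them were the lysosomal glycoprotein Gpnmb at 1368 ± 149.6 TPM, the fatty acid binding protein Fabp5 at 1257 ± 94.1 TPM, the apolipoprotein Apoe at 1069 ± 503 TPM and the protease Lgmn at 597 ± 132 TPM. Apoe was highest in replicate 3, at 1643 TPM against 858 and 706. Others were the complement genes C1qb at 939.6 ± 112 TPM, C1qc at 732 ± 73.6 TPM and C1qa at 227 ± 24.4 TPM, the checkpoint ligand Cd274 at 162 ± 40.4 TPM, Sqstm1 at 262 ± 60.4 TPM, Slfn2 at 369 ± 43.7 TPM and Ccl9 at 137 ± 11.6 TPM. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 expected counts in every library, while Xist stood at 6.61, 2.92 and 11.7 TPM in replicates 1, 2 and 3. The RNA polymerase III transcript Rn7sk, which is mainly nuclear, stood at 22666, 26379.5 and 51782 TPM, and the RNase P RNA Rpph1 at 18843, 28056 and 42488 TPM.

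The labels give the replicates no difference in treatment, so no biological explanation was tested for the patterns between them. Nuclear long noncoding RNAs were highest in replicate 3 and lowest in replicate 2, with Malat1 at a log2 of 1.29 and -1.25 and Neat1 at 1.05 and -1.05 against the mean of the others. The low replicate 2 thus carries part of the ratio of replicate 3, and Gm26917, Gm42418 and CT010467.1, picked by hand and taken to overlap ribosomal RNA, together followed the same order, with 0.256%, 0.0831% and 0.357% of expected counts in replicates 1, 2 and 3. CT010467.1 alone did not, at 224, 34.3 and 136 TPM. Rn7sk and Rpph1 were highest in replicate 3 but lowest in replicate 1. A candidate explanation is carry-over of nuclear RNA into the cytosolic fraction, which would also raise transcripts with retained introns. Their share of protein-coding TPM was 3.15%, 2.99% and 3.66% in replicates 1, 2 and 3, so replicate 3 was 1.16 times the higher of the others, between the limits of 1 and 1.2 set beforehand and leaving carry-over open. By the second quantification the shares were 3.81%, 3.37% and 4.15%, with replicate 3 nearer to the others.

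Immediate-early, feedback and primary cytokine genes were lower in replicate 3, at a median log2 ratio of -0.74 over 54 genes, while the secondary response list had -0.11. A fit on GC content and transcript length over 10233 genes left 0.972 of the median ratio, from -0.73 to -0.71, which argues against that bias as the whole cause. Library scaling, or dilution by nuclear RNA that lowers all cytosolic RNAs alike, would move other genes as much. The medians of 10000 lists matched on mean expression ran from -0.15 to 0.12. This argues against a factor common to all genes as the whole cause. The response genes lay at percentile 0 of these lists, but they were pooled after their values were seen, so nothing is read from the rank. Carry-over that acts unequally on genes was not tested here. A difference in the timing or strength of the response between cultures stays open as an untested hypothesis.

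The mitochondrial gene mt-Co2 was at 0, 4.93 and 0 TPM in replicates 1, 2 and 3 in the alignment-based table. Its nuclear copies Gm28661 (chromosome 1, 24614885 to 24615565, 100.0% identity) and Gm13341 (chromosome 2, 22587291 to 22587962, 95.9%) held 99.6% ± 0.770 (SD, n = 3) of the expected counts of gene and copies together. This share was set as a test before these counts were seen. It shows that the copies held counts, but it is high for any such counts while mt-Co2 is near 0. It thus cannot tell reads of the mitochondrial gene assigned to the copies from reads of the copies. Gm28661 stood at 437 ± 112 TPM. Transcription of the nuclear copies themselves was not excluded.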
